A study of Populus trichocarpa with 2 samples.

How the data were processed

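Small RNA was sequenced from female flower buds labelled as Populus trichocarpa, in 2 libraries (MF and AF) with 1 library per group. Per the labels, the molecule was total RNA and the libraries followed standard Illumina procedures. Each deposited file lists every distinct read sequence (tag) of its library with its length in nt and its raw read count. The authors deposited these counts without normalization. How adapters were trimmed, how reads were filtered and whether molecular identifiers were used are not given in the sources used here. Tags shorter than 18 nt and longer than 44 nt were not in the files, so strongly shortened miRNAs could not be counted. Read lengths given in the files equalled the number of bases in every line, and no sequence occurred more than once in a file.

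No genome was used, and no coordinates are given. MiRNAs were recognised from 99 sequences written down before the data were examined, from general knowledge of plant miRNAs: 70 guide sequences, 2 tasiR-ARF sequences, 19 star sequences and 8 sequences of other organisms as controls. Member letters follow common usage and were not checked against a database. A tag was assigned to a listed sequence when both shared their first 16 nt. Family counts are sums over such tags. They were scaled to all reads of the library as RPM. A family entered the count of 2-fold differences when it had at least 100 reads in either library. Related members that differ only after the first 16 nt share their reads. Tags of 20 to 24 nt outside these groups with at least 100 reads in either library were also compared with guides of the same length, and kept at 2 or fewer changed bases, which was chosen after the data were examined.

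For the 3′ ends, each guide-strand tag was compared base by base with the listed sequences of its group. It was called intact, truncated, extended (full length with up to 8 added bases), or truncated and tailed (a shortened match followed by up to 8 other bases). A tag with 1 internal changed base followed by at least 1 matching base was put in its own class, which was added after the data were examined. A changed last base counted as truncated and tailed. Tails were grouped as U-only, A-only, C-only, G-only or mixed, with T in the files read as U. The planned use of genomic loci to separate templated from untemplated bases could not be made. The tails of miR166 by bases lost were read against miR166a alone, because rare listed relatives have U near the end. This reading and the use of U-only tails of at least 2 nt were also chosen after the data were examined.

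With 1 library per group, no test between the groups was run and no p-value between them is given. RPM values have exact Poisson intervals, shares have exact Clopper-Pearson intervals and ratios have exact conditional binomial intervals, all at 95%. They cover counting error only. For a count of 0, a fixed limit of 3 reads was used, or 0.159 RPM in MF and 0.177 RPM in AF. The exact Poisson interval of 0 reads reaches higher, to 0.196 RPM in MF and 0.217 RPM in AF. Correlations across miRNAs used 100000 two-sided permutations, with Benjamini-Hochberg adjustment over the 2 relations. The listed tags were compared with 10000 random lists of other 20 to 22-nt tags matched on mean RPM in 6 bins, with 1 read added to each count.

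Families and miRNAs named in the text followed a rule fixed before the data were examined: the 10 most abundant families, up to 10 families per direction at or above 2-fold, the 5 miRNAs highest in each 3′ class and the 5 that differed most, and the 5 most abundant tags of each library. Alternatives to scaling, matching, count minimum, template choice and tail definition were computed. The fixed lists of families, 11 in number, included sequences of other organisms.

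The classification was tested on simulated tags, 1400 per class from the 70 guide sequences. Intact, truncated and extended tags were recovered in 100.0% of cases, substitutions in 99.8% and truncated and tailed tags in 86.6%. The interval of the ratio covered the true fold in 95.4% of 1000 simulated families. The simulated tags followed the class rules and the simulated counts were drawn as Poisson, so both are checks of the code. They do not cover PCR copies, unlisted family members or templated bases. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.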

Results

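Small RNAs of poplar (Populus trichocarpa) female flower buds were sequenced in 2 libraries, one labelled MF and one labelled AF, with 1 library per group. What the first letters stand for is not given in the sources used here. The MF library held 18830270 reads in 4295972 distinct sequences (tags), and the AF library held 16980639 reads in 4474068 tags. Tags ran from 18 to 44 nt. Tags seen once made up 78.2% of the MF tags and 79.0% of the AF tags, and carried 17.8% and 20.8% of the reads. The 1112385 tags found in both libraries carried 80.3% of the MF reads and 77.5% of the AF reads. Because each group had 1 library, no difference between them could be set against the spread between replicates. All intervals below are exact 95% intervals that cover counting error only, and PCR copies in the reads would make them too narrow.

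Size classes of the flower bud small RNAs were compared first. The 24-nt class, the length of plant heterochromatic siRNAs, was the most abundant in both libraries, with 35.9% of the MF reads (35.85 to 35.90) and 37.4% of the AF reads (37.33 to 37.37). The 21-nt class, the usual length of plant miRNAs, held 11.4% of the MF reads (11.43 to 11.46) and 18.3% of the AF reads (18.33 to 18.36). The 22-nt class held 10.2% and 14.4%. The 23-nt class held 29.3% in MF and 20.7% in AF, and most of it was a single tag, TACCTGGTTGATCCTGCCAGTAG, the 5′ end of 18S ribosomal RNA by general knowledge, as are the tRNA names below, since no genome was used. That tag alone made up 24.1% of the MF reads and 14.7% of the AF reads. With it left out, the 23-nt class held 6.82% and 7.08%, the 21-nt class 15.1% and 21.5%, and the 24-nt class 47.3% and 43.8%, so that the order of the libraries in the 24-nt share turned round. Reads of 26 to 44 nt made up 6.78% of MF and 1.38% of AF. Of the 24-nt reads, 68.8% in MF and 63.0% in AF began with A, and of the 21-nt reads 54.2% and 57.9% began with U.

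**Figure D1:**
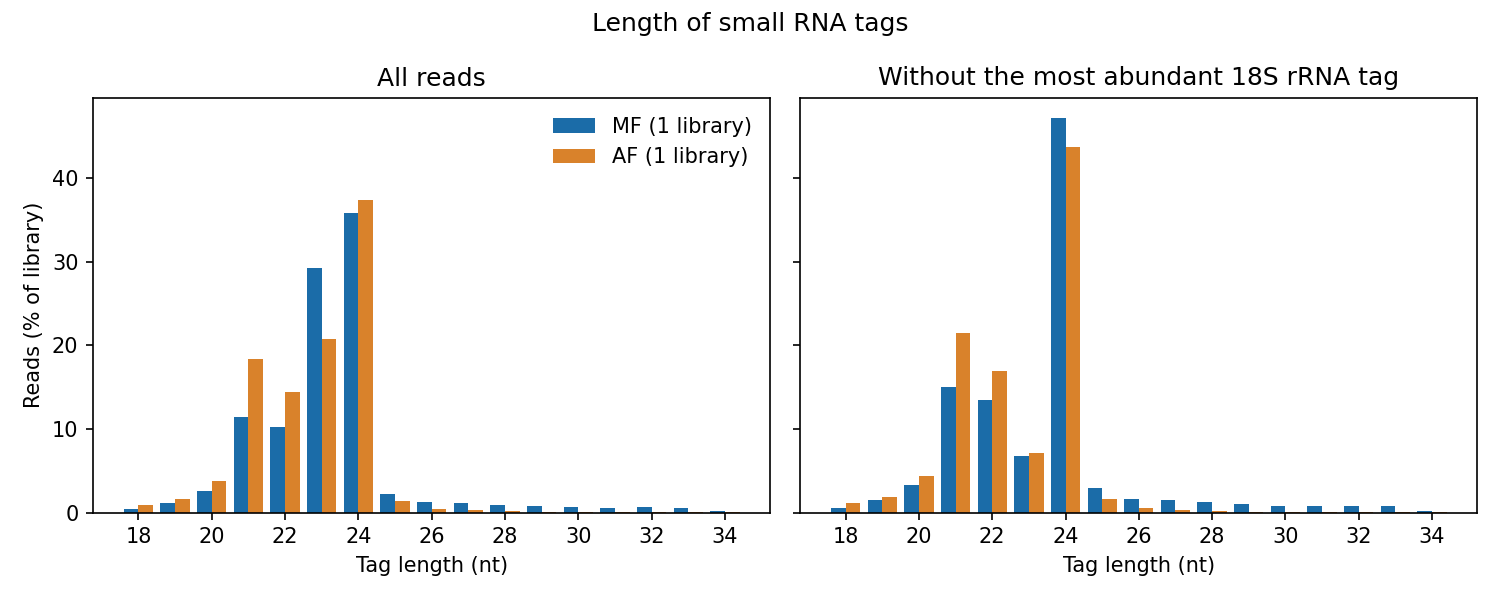
Share of reads (y axis, % of the library) at each tag length from 18 to 34 nt (x axis) in the MF and AF libraries, with all reads (left) and without the most abundant 18S rRNA tag (right). Each bar is 1 library. The 21-nt bar of AF, 18.3%, stands above that of MF, 11.4%, and the 23-nt bar of MF falls from 29.3% to 6.82% when the rRNA tag is left out.

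The 5 most abundant tags of each library were named by rule. After the rRNA tag, both libraries were led by TCGGACCAGGCTTCATTCCCC, the mature miR166a, at 20083 RPM (reads scaled to the library total) in MF and 38871 RPM in AF. GGGGATGTAGCTCAGATGGT, the 5′ end of a tRNA for alanine, was at 5017 and 4575 RPM. The tags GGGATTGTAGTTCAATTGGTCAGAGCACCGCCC and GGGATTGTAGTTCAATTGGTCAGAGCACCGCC, which have the sequence of the 5′ part of the chloroplast tRNA for aspartate, were at 3870 and 3163 RPM in MF and at 342 and 203 RPM in AF, so that they were 11.3-fold and 15.6-fold higher in MF. In the other direction, GGCGGATGTAGCCAAGTGGA, the 5′ end of the chloroplast tRNA for histidine, was at 929 RPM in MF and 6145 RPM in AF, a ratio of 6.61 (6.51 to 6.72). The tag TGGTATGGGCGAGTTGGGAAG, which matched no sequence of the fixed list, was 5.82-fold higher in AF (5.72 to 5.91).

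The abundance of known miRNA families in the 2 flower bud libraries was compared next. Reads of the listed families made up 3.09% of the MF library and 5.60% of the AF library. Of the 21 families with at least 100 reads in either library, 19 had a higher RPM in AF and 2, miR393 and miR159, a higher RPM in MF, with an interval for miR393 that included equality. By identical tags miR393 was higher in AF instead, with 4 reads in MF and 20 in AF. The direction of 8 of these (miR156, miR162, miR164, miR167, miR168, miR319, miR390 and miR403) turned round when ratios were set against the median family, which puts 10 of 21 on each side by construction, and that of miR168 also without the rRNA tag. The number of families at least 2-fold higher in AF was 10 of 21, each with its whole interval above 2, and 0 were at least 2-fold higher in MF. The median ratio of AF to MF over the 21 families was 1.94, or 0.95 on the log2 scale. Relative to that median, 5 families (miR394, miR160, miR396, miR408 and miR530) were at least 2-fold above it and 2 (miR393 and miR159) at least 2-fold below it. MF also held the larger share of the 18S rRNA tag and of reads of 26 to 44 nt, as given above.

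The ratio was largest for miR394, which represses an F-box gene and is needed for stem cell upkeep in the shoot meristem. Its reads numbered 34 in MF and 1040 in AF, or 1.81 and 61.2 RPM, a ratio of 33.9 (24.1 to 49.2). The family miR160, which targets auxin response factors, was at 34.9 RPM in MF and 364 RPM in AF, a ratio of 10.4 (9.60 to 11.3). The family miR396, which targets growth-regulating factors, was at 11.8 and 119 RPM, a ratio of 10.1 (8.75 to 11.6). The copper-responsive miR408 was at 1.70 and 7.54 RPM, a ratio of 4.44 (2.99 to 6.76), and miR397, which targets laccases, was at 25.97 and 81.7 RPM, a ratio of 3.15 (2.84 to 3.50). Tags that begin like miR530 were 3.91-fold higher in AF (3.65 to 4.20), although the listed full sequence of miR530 had no reads. The trans-acting siRNA tasiR-ARF was 3.31-fold higher (2.90 to 3.79), and miR169, which targets NF-Y subunits, was 3.27-fold higher (3.02 to 3.55). The ratio was 2.31 for miR172 (2.27 to 2.36), which targets AP2-type floral regulators, and 2.29 for miR171 (2.20 to 2.38).

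Among the 10 families with the highest mean RPM, ratios ran from 0.823 for miR159 to 10.4 for miR160. The family of miR166 and miR165, which restricts class III HD-ZIP transcripts, held 70.7% of all listed-family reads in MF and 75.7% in AF, and its ratio was 1.94 (1.93 to 1.95). The next were miR390 at 2137 RPM in MF and 2457 RPM in AF, miR167 at 1746 and 2537 RPM, miR156 at 984 and 1824 RPM, miR172 at 837 and 1934 RPM, and miR168 at 1200 and 1292 RPM. The family miR159, which targets GAMYB-type transcription factors, was at 1104 RPM in MF and 909 RPM in AF, a ratio of 0.823 (0.806 to 0.840). For miR164, the values were 453 and 804 RPM, and for miR171 they were 212 and 485 RPM.

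**Figure D2:**
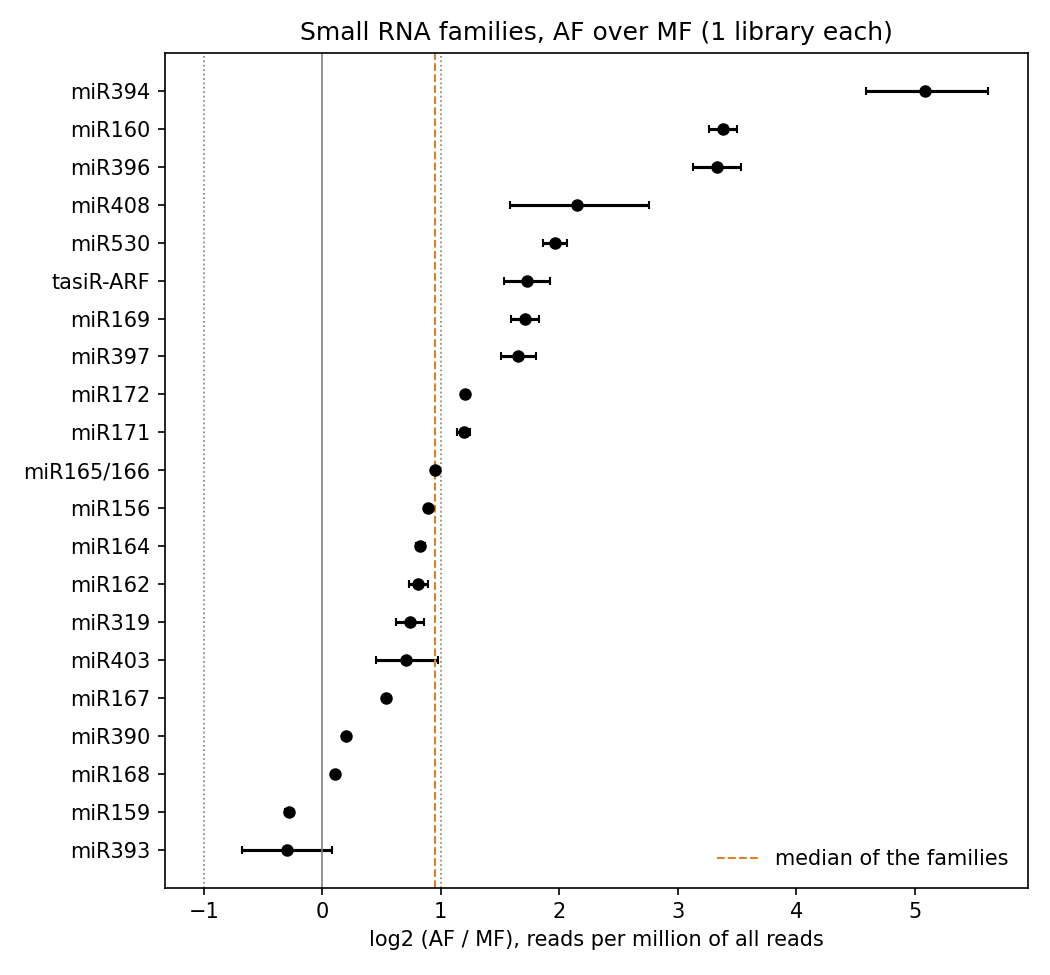
The log2 ratio of AF to MF (x axis, RPM of all reads) of the 21 families with at least 100 reads in either library (y axis). Points are ratios between 1 library each and bars are exact 95% counting intervals. Dotted lines mark a 2-fold difference and the dashed line the median of the families, 0.95. miR394 lies highest at 5.08, and miR393 and miR159 lie below 0.

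By the lists fixed beforehand, all 5 phase change and floral identity families (miR156, miR172, miR159, miR319 and miR171) entered the comparison, and 2 of them, miR172 and miR171, were at least 2-fold higher in AF. Against the median family neither was, and miR159 was at least 2-fold below it. Of the 4 families of meristem, polarity and organ boundaries, miR394 and miR396 were at least 2-fold higher in AF, whereas the miR166 family at 1.94 and miR164 at 1.77 (1.73 to 1.82) were not. Of the 5 auxin-related families, miR160 and tasiR-ARF were at least 2-fold higher, and miR167 at 1.45, miR390 at 1.15 and miR393 at 0.816 (0.626 to 1.06) were not. Against the median family, miR394 and miR396 stayed at least 2-fold higher, as did miR160, whereas tasiR-ARF did not and miR393 was at least 2-fold below. None of the 3 families that feed back on the miRNA pathway reached 2-fold. These were miR162, which targets DCL1, at 1.75, miR168, which targets AGO1, at 1.08, and miR403, which targets AGO2, at 1.64. Of the 4 copper-responsive families, miR397 and miR408 entered the comparison and both were at least 2-fold higher in AF. The others were miR398, with 6 and 43 reads, and miR1444, with none. Of the 7 families put in none of the other lists, miR169 and miR530 entered and both were at least 2-fold higher. Against the median family, miR408 and miR530 stayed at least 2-fold higher and miR397 and miR169 did not.

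Several lists held no family with at least 100 reads in either library by the first 16 nt. Of the phosphate and sulfate families, miR395 had 27 reads in MF and 34 in AF, miR2111 had 29 and 52, miR399 had 0 and 17, and miR827 had none. By its first 16 nt, the NBS-LRR list held reads of miR2118 alone, 11 in MF and 10 in AF. Tags close to that list were abundant, however. TCTTTCCTAGTCCTCCCATTCC, which differed from the listed miR482 at 2 bases, had 19789 reads in MF and 32467 in AF, a ratio of 1.82 (1.79 to 1.85). TCTTTCCTACTCCTCCCATTCC, which differed from it at 1 base, had 4608 and 6118, and TTGCCAATTCCACCCATTCCAA, which differed from the listed miR2118 at 2 bases, had 26880 and 26974 (tags chosen after their values were seen). By the first 16 nt, the list of MYB regulators held 1 read of miR858 in MF and 1 of miR828 in AF. The listed sequences of the PPR-targeting miR475 and miR476 had 0 reads in both libraries, which allows up to 0.159 RPM in MF and 0.177 RPM in AF. In all, 10 of the 39 listed families had no read by their first 16 nt in either library. A family whose listed sequence differs from that of the plant in this part would count as absent under this rule. Tags close to miR827 and miR858 also fell outside it. TTAGATGCCCATCAACGAACA, at 2 bases from the listed miR827, had 307 and 526 reads, and CTCGTTGTCTGTTCGACCTTG, at 1 base from a listed miR858, had 280 and 780. Whether the close tags belong to these families was not tested.

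The passenger (star) strands were compared in the same way. No precursor sequence was used, so no star was tied to the precursor of its guide. The star of miR396 had 99 reads in MF and 730 in AF, a ratio of 8.18 (6.62 to 10.2), beside 10.1 for its guide. The star of miR166 was 2.31-fold higher in AF (2.26 to 2.35), that of miR168 was 1.77-fold higher (1.65 to 1.90), and that of miR162 was 2.86-fold higher (2.38 to 3.45). The star of miR164 was 2.59-fold higher (1.94 to 3.48) beside 1.77 for its guide, and that of miR172, with 9 and 76 reads, 9.36-fold higher (4.68 to 21.3) beside 2.31. The star of miR159 was 3.87-fold higher in AF (3.28 to 4.58), whereas the guide was lower there. The listed star of miR159 had no identical reads and that of miR162 had 0 in MF and 1 in AF, so both ratios rest on tags that share the first 16 nt only. The listed star of miR160 had 923 reads in MF and 766 in AF, a ratio of 0.920 (0.835 to 1.01), beside 10.4 for the guide. The listed stars of miR156, miR167, miR319, miR393, miR398 and miR408 had no reads in either library.

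The 3′ ends of the miRNAs were then examined, since degradation and 3′ modification are the stated subject of the series. Most miRNA reads ended as listed. Intact sequences made up 88.6% of the 581609 assigned reads in MF (88.5 to 88.7) and 89.5% of the 949266 in AF (89.45 to 89.57). Reads shortened at the 3′ end without added bases made up 0.944% in MF (0.920 to 0.970) and 1.02% in AF (0.999 to 1.04). Full-length reads with added bases made up 2.61% and 2.22%, and reads both shortened and given other bases made up 4.69% and 5.08%. Reads with 1 internal changed base made up 3.08% and 2.16%. No genome was used, so an added base can be templated by the precursor, and a changed base can belong to an unlisted family member.

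A few tags carried most of these variants. Of the reads of the miR166 group, 4.13% in MF and 4.48% in AF were TCGGACCAGGCTTCATTCCCG, which has G as its last base. For miR390, 29.7% and 26.01% of the reads were AAGCTCAGGAGGGATAGCACC. For miR167, TGAAGCTGCCAGCATGATCTTA held 11.9% of the reads in MF and 23.4% in AF, and TGAAGCTGCCAGCATGATCTGA held 14.2% and 5.60%, so that the 2 forms with a final A stood in opposite order in the libraries. For miR156a, TGACAGAAGAGAGTGAGCACA held 13.2% in MF and 22.1% in AF. When the 54 tags that reached 1% of the intact reads of their miRNA were left out, intact reads made up 95.9% in MF and 96.2% in AF, and shortened and tailed reads fell to 1.48% and 1.24%.

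Among all reads with added bases, G-only tails made up 40.6% in MF and 47.0% in AF, A-only tails 29.4% and 25.6%, U-only tails 15.1% and 13.6%, and C-only tails 2.83% and 2.22%. Most G-only tails were the miR166 tag above, and without the miR166 family the G-only share was 1.31% and 1.15%. Added bases on full-length miRNAs were mostly A, at 77.4% in MF and 79.7% in AF, and U made up 10.3% and 11.5% of them. The 2 miR167 tags above, with 3920 and 4669 reads in MF and 10070 and 2413 in AF, carried most of the 11768 and 16814 A-only reads, and count as extended only through rare listed relatives. With 1 template per group, full-length reads with added bases were 1.06% and 0.824% of reads. In that setting A-only tails were 8.62% and 7.19% of all tails, shortened miRNAs included, beside 29.4% and 25.6% above. The A-only share of tails on full-length miRNAs alone is not given for that setting. The class of shortened miRNAs with at least 2 added bases differed from the full-length ones. In that class, 3295 reads in MF and 4578 in AF had U-only tails. A-only tails had 29 and 32, C-only tails 7 and 2, and G-only tails 4 and 3. U-only tails were thus 44.8% of this class in MF (43.6 to 45.9) and 38.9% in AF (38.0 to 39.7), with nearly all of the remainder of mixed composition. Without the miR166 family, U-only tails were 273 of 2619 reads of this class in MF and 321 of 5161 in AF. A-only tails were 15 and 16, and the miR530 tags are included in these totals. When tails of that length on full-length miRNAs were added, U-only and A-only tails without the miR166 family were 459 and 474 reads in MF, and 613 and 321 in AF.

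The miR166a sequence carried most of the U tails, mostly after the loss of 4 bases. Read against miR166a alone, U-only tails of 2 nt on molecules that had lost 4 bases had 1759 reads in MF and 2378 in AF. Tails of 3 nt at the same point had 682 and 1068 reads, of 4 nt 354 and 528, of 5 nt 161 and 216, and of 6 nt 53 and 55. Single U bases on molecules that had lost 3 bases had 781 and 1021 reads. Full-length miR166a with 1 added U had 350 and 511 reads, and with 2 added U bases 11 and 7. The last bases left after the loss of 4 are themselves U, so a molecule that lost more bases before U was added would be read in the same way. Molecules shorter than 18 nt in total were outside the range of the files.

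**Figure D3:**
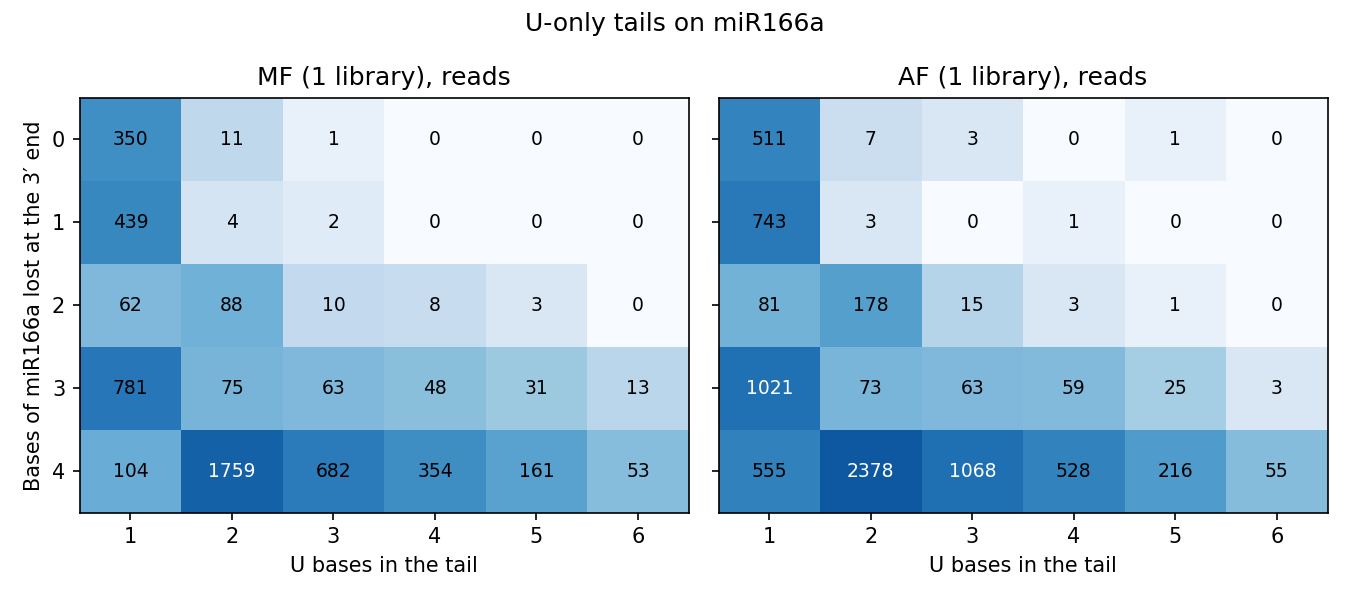
Reads of miR166a by bases lost at the 3′ end (y axis) and by the length of the U-only tail (x axis, nt), in MF (left) and AF (right), 1 library each. Each cell prints its read count, and its colour follows the count on a log scale. The cell with 4 bases lost and 2 U bases added holds the most reads, 1759 in MF and 2378 in AF.

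Individual miRNAs differed widely in these shares, and are given in the order of the mean of the libraries. Among miRNAs with at least 1000 reads in each library, miR159a had the highest truncated share, 5.42% in MF (5.11 to 5.74) and 6.11% in AF (5.740 to 6.502). It was followed by miR166a at 0.875% and 1.06%, miR171a at 1.16% (0.834 to 1.56) and 0.606% (0.444 to 0.808), miR390a at 0.537% and 0.748%, and miR167a at 0.581% and 0.624%. The truncated share was higher in AF for 10 of 11 miRNAs, with miR171a as the exception. The intervals of the libraries did not overlap for miR159a, miR166a, miR171a and miR390a, and overlapped for the others. The difference was largest for miR159a, at 0.69 percentage points, followed by miR171a, miR390a, miR164a and miR166a. The share with added bases was highest for miR167a, at 28.4% in MF (27.9 to 28.9) and 31.8% in AF (31.3 to 32.2), then for miR156a at 14.2% and 23.1%, miR159a at 17.5% and 14.7%, miR166a at 6.02% and 5.99%, and miR162a at 5.17% and 5.99%. The largest differences in this share were those of miR156a, miR167a, miR159a, miR162a and miR156g, the last at 3.49% and 4.30%. The highest share of all, 99.8% in MF and 99.97% in AF, was that of the miR530 group, whose listed sequence had no reads, so that it was set aside in the comparisons of 11 miRNAs.

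The U-only tails of at least 2 nt were also uneven, which was seen after the values were known. They made up 1.27% of the reads of miR162a in MF (0.831 to 1.85) and 1.36% in AF (0.988 to 1.82), 0.765% and 0.920% for miR159a, 0.740% and 0.594% for miR166a, and 0.533% and 0.611% for miR156g. For miR172a they made up 0.0064% and 0.012%, with 1 and 4 reads. Tails on full-length molecules are included in these shares. For miR156g these were 71 and 126 reads, beside 4 and 7 on shortened molecules. For miR166a they were 23 and 15, beside 3022 and 4257. U-only tails outnumbered A-, C- and G-only tails of that length together in 5 of the 11 miRNAs in MF and in 6 of 11 in AF.

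**Figure D4:**
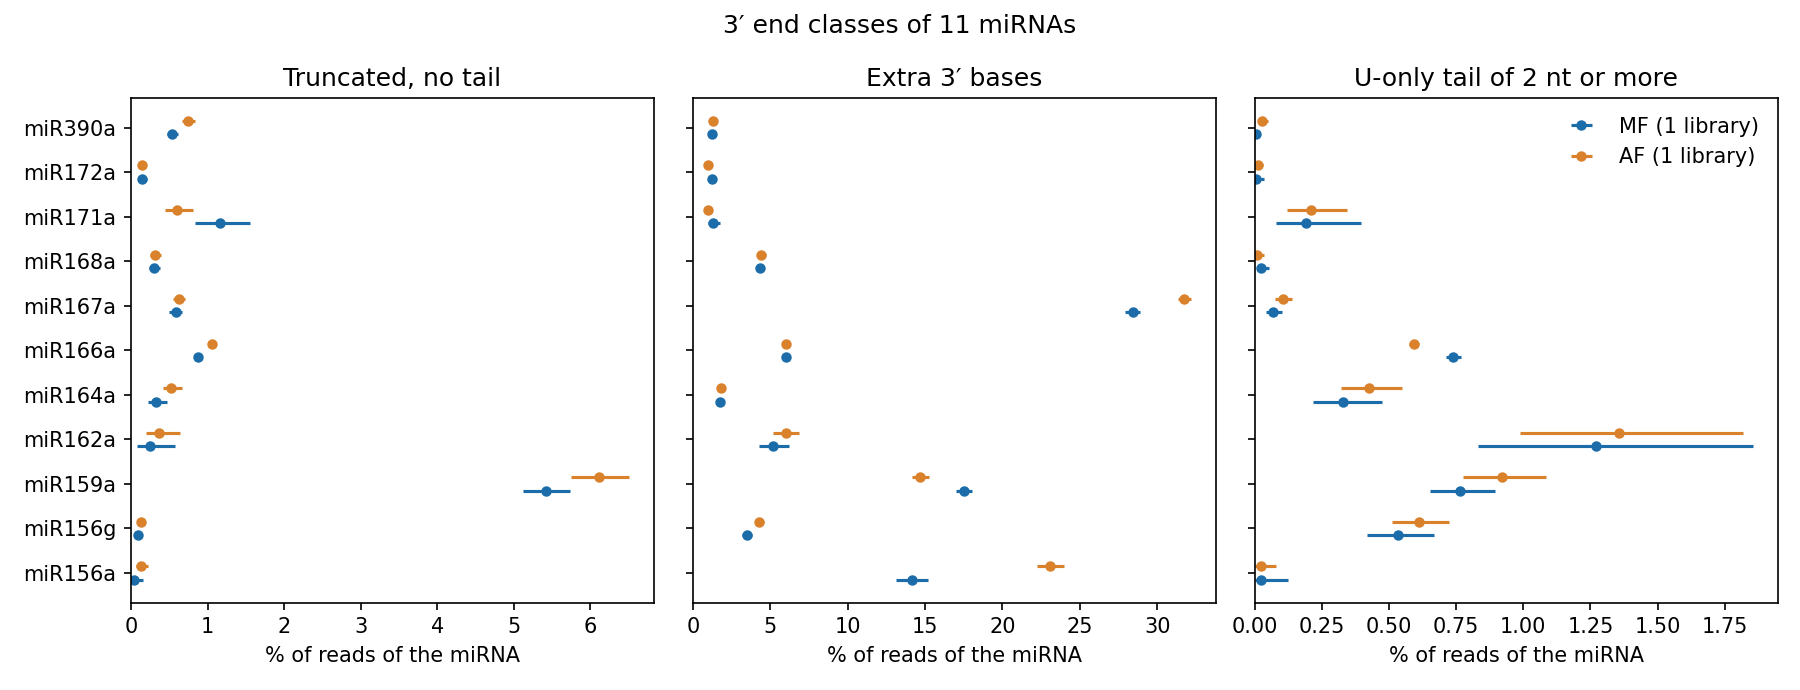
Share of the reads of each of 11 miRNAs (x axis, %) that were truncated without a tail (left), had extra 3′ bases (middle) or had a U-only tail of at least 2 nt (right), in MF and AF. Points are 1 library each and bars are exact 95% binomial intervals. miR159a stands out in the left panel at 5.42% and 6.11%, and miR167a in the middle panel at 28.4% and 31.8%.

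Across 12 miRNAs, the truncated shares of the libraries had a Pearson r of 0.991 (permutation p = 0.00014, adjusted 0.00014) and a Spearman rho of 0.916 (permutation p = 6e-05, adjusted 6e-05). The shares with added bases had r of 0.995 (permutation p = 3e-05, adjusted 6e-05) and rho of 0.972 (permutation p = 1e-05, the smallest that the permutations can give, adjusted 2e-05). These were 2 two-sided relations across miRNAs, which are not independent replicates. Without miR530a, whose listed sequence had no reads, r was 0.991 for truncation (permutation p = 0.00051) and 0.962 for added bases (permutation p = 0.00044). Without the 2 miRNAs farthest from the median in MF, r was 0.970 for truncation (without miR171a and miR159a, permutation p = 4e-05) and 0.912 for added bases (without miR167a and miR530a, permutation p = 0.0051).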

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

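Reads of sequences that were listed as controls from other organisms exceeded the limit of 3 reads set for a count of 0. The human and animal let-7a sequence had 13 identical reads in AF (0.766 RPM) and 1 in MF, and 42 and 3 reads when its first 16 nt alone were matched. The sequence of miR528, listed as a monocot miRNA, had 30 identical reads in MF (1.59 RPM) and 46 in AF (2.71 RPM). The listed miR-21, miR-122, miR-16, bantam, miR444a and miR824 had 0 identical reads in both libraries. None entered a comparison between the libraries, and the source of these reads was not tested.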

How the results depend on the processing

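Tests marked here as added were chosen after the data were seen: leaving out the 18S rRNA tag, scaling to 24-nt reads, counting substitutions as tails, leaving out groups whose listed sequence is not the top tag or tags at 1% of intact reads, a sole template per group, correlations without miR530a, and tails of at least 2 nt. The count of 10 families at least 2-fold apart was 7 under the median of family ratios and under scaling to all family reads, where 5 were higher in AF and 2 in MF. It was 9 with identical tags, 12 with a minimum of 10 reads, 8 with a minimum of 1000 reads, and 10 without the rRNA tag and under 24-nt scaling, all higher in AF. None of the 10 families at or above 2-fold changed sign in the settings that gave it a value (miR530 had none with identical tags), but miR171, miR172, miR169, miR397 and tasiR-ARF fell under 2-fold against the median and the family reads. The families higher in AF were 10 against the median, with 10 lower and 1 at 0, a balance that centring on the median sets by construction, and 12 of 21 against all family reads. The scaling to the median lowers every log2 ratio by 0.95, and scaling to family reads by 0.86. Counted as distinct tags, the 21-nt share was 8.59% in MF and 10.7% in AF, and the 24-nt share 63.4% and 62.8%. With tags of at least 2 reads, the 21-nt share was 12.1% in MF and 20.4% in AF, and the 24-nt share 29.96% and 30.5%. Without the rRNA tag, the 21-nt share was 15.1% in MF and 21.5% in AF, and the 24-nt share 47.3% and 43.8%. As an unweighted mean over miRNAs, the shares (MF and AF) were intact 80.4 and 79.6%, truncated 0.817 and 0.896%, extended 5.21 and 5.86%, truncated and tailed 10.2 and 10.4%. That mean includes miR530a, whose listed sequence had no reads, at 0% intact and 99.7 and 99.9% truncated and tailed. Most of the mean truncated and tailed share comes from it. With a shared part of 18 nt, the shares (MF and AF) were intact 89.8 and 90.7%, truncated and tailed 3.85 and 4.34%. Without reads changed at the last base only, the shares (MF and AF) were intact 91.5 and 92.9%, truncated 0.976 and 1.06%, extended 2.7 and 2.3%, truncated and tailed 1.55 and 1.53%. With substitutions counted as tails, the shares (MF and AF) were truncated and tailed 7.77 and 7.24%. Without groups whose listed sequence is not the top tag, the shares (MF and AF) were intact 88.8 and 89.9%, truncated and tailed 4.49 and 4.69%. Without tags at 1% of intact reads, the shares (MF and AF) were intact 95.9 and 96.2%, truncated 0.747 and 0.935%, extended 0.793 and 0.56%, truncated and tailed 1.48 and 1.24%. With 1 template per group, the shares (MF and AF) were intact 88.4 and 89.2%, truncated 0.886 and 0.956%, extended 1.06 and 0.824%, truncated and tailed 6.59 and 6.83%. Among tails of 1 nt, tails were U-only in 8.72 and 8.12%, A-only in 35.7 and 31%, G-only in 52 and 58.2%. Without the miR166 family, tails were U-only in 11.9 and 11.7%, A-only in 62 and 61.2%, G-only in 1.31 and 1.15%. On full-length miRNAs, tails were U-only in 10.3 and 11.5%, A-only in 77.4 and 79.7%, G-only in 1.39 and 1.28%. Among tails of at least 2 nt, with the miR530 group included, tails were U-only in 37.6 and 36.7%, A-only in 6.65 and 3.29%, G-only in 0.0859 and 0.0301%. Without tags at 1% of intact reads, tails were U-only in 43.8 and 51.1%, A-only in 17.6 and 16%, G-only in 2.19 and 2.31%. With 1 template per group, tails were U-only in 17.7 and 16.2%, A-only in 8.62 and 7.19%, G-only in 39.3 and 45.5%. Pearson's r between libraries, for the truncated share and the share with added bases, was 0.989 and 0.993 with at least 100 reads per miRNA, 0.991 and 0.995 with a shared part of 18 nt, and 0.991 and 0.962 without miR530a. It was 0.970 and 0.912 without the 2 miRNAs farthest from the median in MF, as given above. Other settings were not run for it. The cause of these differences between settings was not tested. The restriction to tags matching the genome was not run, and templates from the listed sequences alone were the setting used throughout. No paired analysis was possible because each group held 1 library and the labels give no replicate number. Depth limits families under 100 reads, such as miR398, miR395 and miR399.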

Other observations

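Tests in this part were chosen after the result was seen, except the comparison with random lists. Several abundant 21 and 22-nt tags outside the fixed list were also higher in AF, and are given by sequence because the list does not name them (chosen after their values were seen). GGAATGGGCTGTTTGGGATGA was at 495 RPM in MF and 2292 RPM in AF, a ratio of 4.63 (4.53 to 4.74). TCCCTACTCCGCCCATGCCATA was 3.02-fold higher (2.95 to 3.10), TTCCCAAAGCCGCCCATTCCAA 2.52-fold (2.45 to 2.59) and TTATACAGAGTAATCACGGTCG 2.41-fold (2.36 to 2.45). TTGCCAATTCCACCCATTCCAA was at 1427 and 1589 RPM, a ratio of 1.11 (1.09 to 1.13). Of the 2186 unlisted 21-nt tags with at least 100 reads in either library, 641 were at least 2-fold higher in AF and 63 in MF, with a median log2 ratio of 0.54. Of the 5431 such tags of 24 nt, 703 were at least 2-fold higher in AF and 785 in MF, with a median of -0.10.

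The listed families were mostly higher in AF, with a median log2 ratio of 0.95. Dilution of MF by the 18S rRNA tag cannot be the whole cause, since the median was 0.79 with that tag out of the totals. It was 0.66 when the totals held only 20 to 24-nt reads without the tag. A gain shared by all 20 to 22-nt tags is also not enough. The 26 listed tags had a median of 1.09, at percentile 100 of 10000 matched random lists, whose central 95% ran from 0.05 to 0.68. These lists were matched on mean RPM and not on length. The medians of unlisted tags were 0.18 at 20 nt, 0.54 at 21 nt and 0.43 at 22 nt. A gain of the 21-nt class alone was thus not tested. A difference between the bud types, between the 2 RNA preparations or between the 2 libraries stays open, as 1 library per group cannot separate them.

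U-only tails of at least 2 nt on shortened miRNAs may reflect uridylation, which plants are known to apply to unprotected miRNAs, and this is a hypothesis. Sequencing errors in shortened miRNAs are argued against as the whole cause. Such reads were 63.3 times in MF and 108 times in AF those expected if each changed base arose at the highest rate of change to U in the first 16 nt of the same miRNA. Without the miR166 family these values were 6.31 and 9.67. Bases left by trimming were weighed by the share of U-only tailed reads among these and untailed reads, with other tails left out. That share was 925 times as high in MF and 890 times in AF among shortened molecules as among full-length ones. Without the miR166 family it was 92.7 and 86.5 times as high. Untailed reads under 18 nt, the length of most miR166a remnants with U tails, are outside the files, which can raise these ratios. On miR166a 3 bases short, which is within the files, 2-nt U tails had 75 and 73 reads beside 205 and 826 untailed. On full-length miR166a they had 11 and 7 beside 378160 and 660055, which argues against trimming for these reads. The miR166 family alone does not account for the tails. Without it, U-only tails on shortened miRNAs still outnumbered A-, C- and G-only tails together by 11.4 to 1 in MF and 16.9 to 1 in AF, over 273 and 321 U-only reads. Most of these came from miR159a, with 115 and 104, and miR171b, with 75 and 73, whose listed sequence is not its top tag. Without the miRNAs whose listed sequence is not the top tag the ratios were 8.17 and 12.6, and without miR159 as well 6.08 and 16.9, over 73 and 135 U-only reads. The abundant miR390a, miR172a and miR167a had 0 to 4 such reads in each library. On full-length molecules, miR167a had 22 and 45 reads with U-only tails of at least 2 nt. Mixed tails were the larger part of tails of that length on shortened miRNAs, at 54.7% in MF and 60.8% in AF. That holds only with 2 miR530 tags counted, whose listed sequence had no reads. They had 727 and 221 reads in MF and 2757 and 629 in AF. Without them, U-only tails would outnumber mixed tails in both libraries, but only through the miR166 family. Outside that family, mixed tails had 2322 reads in MF and 4821 in AF, beside 273 and 321 U-only. Mixed tails would still lead there with the 2 miR530 tags left out. With tails on full-length miRNAs included, U-only tails no longer led A-only ones without the miR166 family in MF, at 459 reads beside 474. Bases templated by unlisted precursors stay open without a genome.

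The form of miR166 that ends in G is a candidate for an unlisted family member. Its share was 4.30% of last-base C and G reads in MF and 4.65% in AF, which was 7.40 and 7.93 times the highest share of G at any other C of the sequence, which argues against sequencing error as the cause. A general addition of G to miRNAs shortened by 1 nt was not seen. G was the most frequent changed last base in at most 1 of 11 other miRNAs, or 9.09%. That was miR530a, whose listed form had no reads and in which G led in AF and was tied with C at 2 reads each in MF. Of the 11, miR162a itself ends in G, and the miR167 and miR172 groups list members that end in G. In these G could not count as a changed base, so they could not show such an addition. A second locus and a miR166-specific modification were not told apart by any value here.

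The listed sequences of 5 families described in poplar (miR475, miR476, miR1444, miR1446 and miR1450) had 0 reads in both libraries, even by their first 16 nt. No tag of the same length within 2 changed bases of them reached 100 reads in a library. Expression under the limit of 0.177 RPM that 0 reads allow cannot be told apart from absence. A plant other than the labelled one is a possible explanation. It cannot be told apart from sequences misremembered in the list or from families silent in these buds, because 0 reads are the same under each. Of other plants the list held only monocot and Brassica sequences, of which miR528 had 30 and 46 identical reads and miR444a and miR824 had 0.

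The guide of miR160 was 10.4-fold higher in AF while its listed star was at 49.0 RPM in MF and 45.1 RPM in AF. The star made up 58.4% of guide and star reads in MF (55.9 to 60.8) and 11.04% in AF (10.3 to 11.8), so that the ratio of guides to stars changed by 3.50 on the log2 scale. This exceeded in size the change of each of the other 6 families with at least 50 star reads in each library. The largest of these was -2.23, for miR159, whose star was matched by its first 16 nt alone. The ratio also fell for miR168 (-0.71), miR162 (-0.71), miR164 (-0.54) and miR166 (-0.25), and rose for miR396 alone (0.30). Several miR160 precursors with different stars could give the pattern of miR160, and that was not tested here.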
